A study of Homo sapiens with 18 samples.

How the data were processed

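RNA of human monocyte-derived macrophages was measured on 18 Affymetrix Human Gene 1.0 ST arrays, in 6 groups of 3 arrays each. Per the labels' protocols, monocytes were differentiated for 8 days with 25 ng/ml M-CSF. Lymphocytes were kept for 7 days with 50 U/ml IL-2 and irradiated with 10 Gy to give early apoptotic lymphocytes (EAL) or late apoptotic lymphocytes (LAL), used with or without a coat of C1q. Macrophages were kept with these targets for 1 h and then with 10 ng/ml LPS for 3 h. The groups were unstimulated macrophages, LPS alone, EAL with LPS, C1q-coated EAL with LPS, LAL with LPS, and C1q-coated LAL with LPS. The labels name no donor of any array, so the p-values measure only the spread between arrays, which may be technical. The labels of 4 arrays carry the mark "re", whose meaning is not stated: 1 with LPS, 1 with C1q-EAL and 2 with LAL.

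Per the series design text, the authors processed the arrays in JMP Genomics 5.0 and compared each group with unstimulated macrophages by analysis of variance with Holm adjustment at an alpha of 0.05. The deposited value table holds log2 background-corrected intensity for 253318 probe sets on 18 arrays, a unit read from the values because the labels do not state it. On each array the spacing of tied low values followed log2 of a whole step of intensity with an error of 2.1e-06 to 2.8e-06, against 0.0442 to 0.1341 for a natural log and 0.196 to 0.443 for log10. Each array carried a constant of its own, from -7.103 to -6.071. Array medians ran from 0.655 to 0.902 and interquartile ranges from 3.153 to 4.301 log2, so the arrays had not been brought to a shared distribution. A further deposited table gives a signed value per group for 2235 rows with 2210 probe sets, on a scale that the file does not state. Its values served for gene names only. Among 86 rows that moved 1 way in all 5 treated groups in both tables, by over 1 log2 in the value table, 60 (69.8%) had opposite signs. Over 2 log2 the number was 17 of 31 (54.8%). Every direction given here is treated minus comparison group in the value table.

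The value table was quantile normalized over all probe sets with limma 3.58.1 in R 4.3.3. Probe sets were given the symbol of the authors' deposited table, in which 428 rows have none, and 1795 had exactly 1 symbol. Symbols were current for 1446 probe sets, were updated through their RefSeq accession for 182 and through an older symbol for 83, and stayed as deposited for 84. The mean over probe sets gave 1767 genes, 28 of them from more than 1 probe set. Any other gene rests on 1 probe set picked by the authors, and its change is that of this probe set only. Whether a probe set reads a whole transcript or a part of it was not tested. Probe sets averaged for a gene could differ, as for LIMK2 with LPS against unstimulated (0.1 and 3.42 log2), or lie close, as for PLAC8 with EAL against LPS (3.36 and 2.97). A gene was tested if at least 3 of the 18 arrays lay above the 25th percentile of that array, which left 1498 genes and removed 269. The authors chose these probe sets on the same arrays, so neither the counts nor the gene list tests are independent evidence of a direction, and shares among them do not describe the whole transcriptome. Tables were read with version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

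A limma model with 1 mean per group was fitted to all 18 arrays, with a variance trend in the empirical Bayes step. Each comparison was tested with limma's moderated test, two-sided, and Benjamini-Hochberg adjustment over the 1498 genes. A gene passed at an adjusted p under 0.05, and errors beside log2 changes are standard errors of that model with n = 3 arrays per group. The median standard error was 0.288 log2 for 3 arrays against 3, 0.204 for contrasts averaged over pairs of groups and 0.408 for the interaction of C1q with the kind of target. The number of arrays limits this precision.

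Gene lists were fixed with the design. The 15 lists with at least 3 tested members were interferon-stimulated genes, pro-inflammatory cytokines, immunoregulatory mediators, inflammasome components, JAK-STAT signalling, chemokines, chemotactic receptors, the Toll-like receptor pathway, costimulation and classical (M1) markers, MHC and antigen presentation, metallothioneins, p53 target genes, T cell markers, NK and cytotoxic cell markers, and B cell markers. They were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other tested genes, and adjusted over the lists of a comparison. The same test was run with a correlation estimated from the data, and fry as an alternative. Members were also counted adjusted over the list alone. Lists with 1 or 2 tested members were counted without a test. The genes named per comparison were the 8 with the largest rise and the 8 with the largest fall among genes that passed and whose groups did not overlap; where fewer than 5 genes passed, the 5 with the smallest p; a fixed panel of 20 cytokine, inflammasome and interferon genes; and up to 4 members with the smallest p of each list that passed or held a member that passed. Y-linked genes, XIST and names of clones were left out of this naming. The sets of samples, comparisons, tests, lists, this rule and the alternatives listed next were chosen before the data were examined.

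Alternatives covered the filter (none, or the 50th percentile), the values as deposited, arrays centred on their medians, the probe set with the highest mean in place of the mean, the replicate number as a block, the mark "re" as a covariate, only the arrays compared, array weights, the analysis of variance that the submitters describe with Holm or Benjamini-Hochberg adjustment, and each array left out in turn. Chosen only after seeing the data were an offset of 50 intensity units before the log, all probe sets in place of named genes, only the 14 arrays without the mark "re", C1q-LAL replicate 1 left out of every comparison, and the gene list tests and the correlation of C1q effects under further settings. Replicate numbers did not pair the arrays: 45 pairs of arrays with the same number had correlations of their deviations from -0.23 to 0.23, with a mean of -0.01 against 0.01 for different numbers.

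The gene test was tested on simulated data with the real mean and residual spread of each gene and normal noise, with 200 changed genes in each of 10 simulations per comparison of 1498 genes. For EAL with LPS against LPS it recovered 13.8% of genes changed by 0.5 log2, 60.8% at 1, 93.6% at 2 and 99.4% at 4. For C1q-EAL against EAL it recovered 16.6%, 59.8%, 92.6% and 99.8%. For C1q averaged over both targets the shares were 37.2%, 82.2%, 98.4% and 100%, and for LAL against EAL they were 36%, 80.6%, 97.8% and 100%. For the interaction they were 6%, 32.4%, 83.8% and 98.2%. Between 3.2% and 4.8% of calls were false. These shares hold for 200 changed genes. With few changed genes the adjustment is stricter and fewer of them would be recovered. The shares therefore do not give the power of the C1q comparisons, which called 0 or 1 gene on the real arrays. The list test called all 15 simulated lists shifted by 1 log2, and 1 of 202 unchanged lists. Genes were simulated independently of each other. The simulation therefore does not give the false rate for lists whose members are correlated on the real arrays.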

Results

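The 18 arrays held 3 each of unstimulated macrophages, macrophages with LPS alone, and macrophages given EAL, C1q-EAL, LAL or C1q-LAL for 1 h before LPS. C1q is the recognition molecule of the classical complement pathway and binds dying cells. The comparisons ask how macrophages respond to LPS, how early and late apoptotic lymphocytes change that response, and how C1q on the targets changes it further. Arrays with targets may also hold RNA of the added lymphocytes, because the labels name no wash or sort that would remove them. Log2 changes are treated minus comparison group in the value table, and in many rows this direction opposes the sign in the authors' deposited table, whose scale is not stated. Of the fixed panel, 12 genes were tested. TNF, PYCARD, CASP1, IFNB1, RSAD2 and CCL2 were among those not analysed here, and IL37 did not pass the filter.

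LPS alone raised pro-inflammatory cytokines. Among them, IL12B, a subunit of IL-12 and IL-23, rose by 5.49 ± 0.15 log2 (45.1-fold; SE, n = 3 per group; adjusted p = 7.5e-16). IL23A, the other subunit of IL-23, rose by 4.90 ± 0.15, IL36G by 3.94 ± 0.19 and IL6 by 3.36 ± 0.25. IL10, an anti-inflammatory cytokine, rose by 3.04 ± 0.15 and the serine protease inhibitor SERPINB4 by 8.03 ± 0.26. MMP3, a matrix metalloproteinase, rose by 6.44 ± 0.31, WNT5A by 4.65 ± 0.24 and IL20 by 4.74 ± 0.35. The probe sets averaged for IL20 differed, at 2.82 and 6.67. Of the 1498 genes, 139 were higher and 21 lower than in unstimulated macrophages (2854 and 700 over all probe sets). Different probe sets can read the same gene, as for IL20. Counts over all probe sets, here and below, are therefore not counts of genes.

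**Figure D1:**
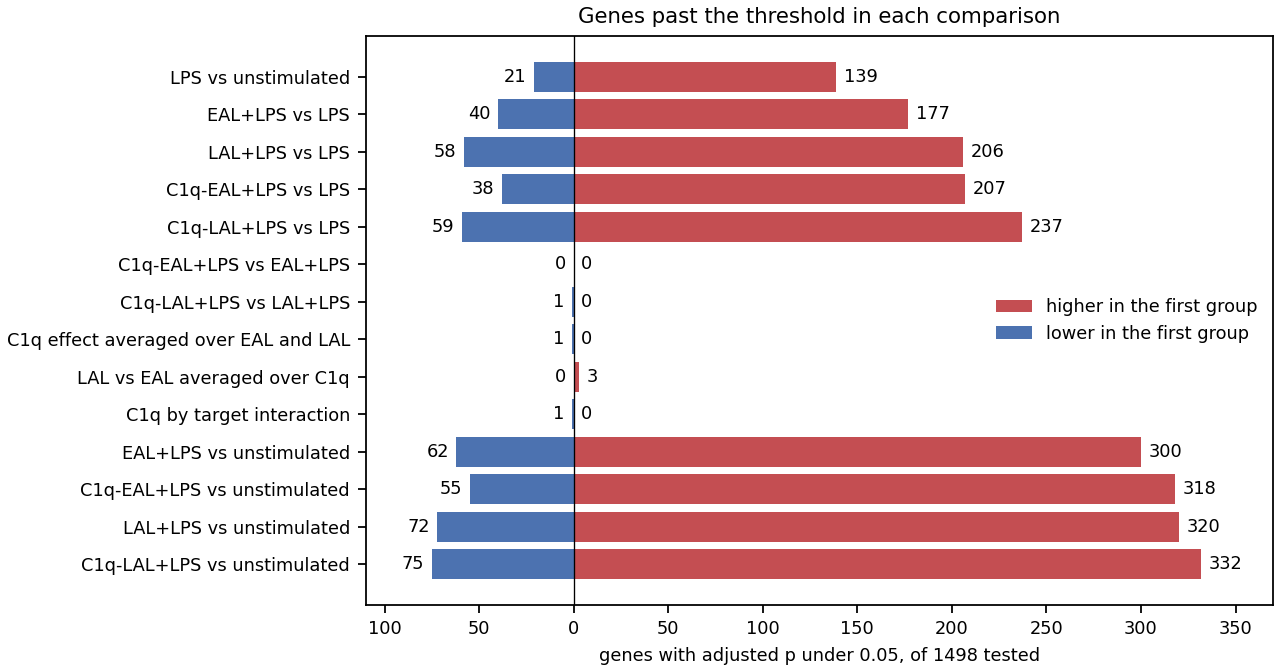
Number of genes past an adjusted p of 0.05 in limma, of 1498 tested, for each comparison. Bars to the right count genes higher in the first group and bars to the left genes lower in it: target groups against LPS reach 217 to 296 genes in all, and C1q-coated against uncoated targets 0 or 1.

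Of the 8 tested pro-inflammatory cytokines, 6 rose with LPS and none fell, and 6 passed when adjusted over the list alone (camera adjusted p = 2.6e-14). Of 9 metallothioneins, which bind zinc and copper, 7 rose, and 7 adjusted over the list alone (camera adjusted p = 2.6e-14), with MT1M at 5.90 ± 0.23, MT1E at 2.93 ± 0.10 and MT1F at 2.48 ± 0.10. Probe sets of this family, and those of SERPINB4, may also read near-identical relatives. Of 7 costimulation and classical (M1) markers, 6 rose, and 7 adjusted over the list alone, among them CCR7 (1.75 ± 0.20), the receptor that guides cells to lymph nodes, and the ectoenzyme CD38 (1.15 ± 0.15; camera adjusted p = 3.3e-12). Of 8 chemokines, 4 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0072), led by CCL19 at 3.86 ± 0.19 and with CCL5 at 1.46 ± 0.11. Of 4 inflammasome components, 3 rose, and 3 adjusted over the list alone (camera adjusted p = 0.00476): CASP5 by 2.86 ± 0.18, NLRP3 by 1.25 ± 0.32 and IL1B by 0.71 ± 0.08. The probe sets averaged for CASP5 stood at 3.74 and 1.98. These list calls also held with an estimated correlation. The call of NLRP3 was lost without unstimulated replicate 3 (1.17) and on arrays without the mark "re" (1.12).

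Antigen presentation went the other way. Of 5 tested genes of MHC and antigen presentation, 2 fell and none rose, and 2 passed when adjusted over the list alone (camera adjusted p = 0.00743, and 0.0354 with an estimated correlation). HLA-DQB1 changed by -1.13 ± 0.17 and HLA-DQA1 by -0.97 ± 0.16, both parts of the class II molecules that present peptides to helper T cells. TLR5, the receptor for bacterial flagellin, fell by 1.24 ± 0.20, DCSTAMP, needed for fusion into multinucleated cells, by 1.27 ± 0.24, and TREM2, a lipid-binding receptor, by 0.73 ± 0.16. The largest falls were MYO18A at -2.18 ± 0.67, GDAP1 at -1.98 ± 0.58, TMA16 at -1.78 ± 0.45 and TRIM34 at -1.62 ± 0.49. Both inhibitors of cytokine signalling SOCS1 (1.02 ± 0.18) and SOCS3 (1.02 ± 0.16) rose. JAK3 rose by 0.98 ± 0.29, which made 3 of 6 JAK-STAT genes, and 3 adjusted over the list alone (camera adjusted p = 0.0562). Calls were lost without LPS replicate 2, LPS replicate 3 or unstimulated replicate 2 for MYO18A (-1.69, -1.96, -2.06), GDAP1 (-1.53, -1.95, -1.69), TRIM34 (-1.42, -1.52, -1.62) and JAK3 (1.00, 0.90, 0.92), and without the latter 2 for TMA16 (-1.11, -1.57). Calls were also lost without unstimulated replicate 1 for MYO18A (-2.39), TRIM34 (-1.39) and JAK3 (0.99), without unstimulated replicate 3 for MYO18A (-2.07), GDAP1 (-2.10) and JAK3 (1.04), and on the values as deposited for TREM2.

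Of 8 immunoregulatory mediators, 3 rose with LPS, and 3 adjusted over the list alone: IL10, IL2RA (2.75 ± 0.42) and PTGES (1.04 ± 0.24; camera adjusted p = 0.0562). Of 7 chemotactic receptors, 2 rose, and 2 adjusted over the list alone, with FPR2, a receptor for formylated peptides, at 2.67 ± 0.31 (camera adjusted p = 0.0562). Of 9 interferon-stimulated genes, ISG20 (1.23 ± 0.22) and IFITM1 (0.71 ± 0.19) rose, and 3 passed adjusted over the list alone; the list median was -0.35, its mean 0.01 and its test pointed down (camera adjusted p = 0.523). IL27 stood at 0.01 ± 0.25 (adjusted p = 0.986), EBI3 at 0.39 ± 0.19 (adjusted p = 0.284), CXCL10 at -0.38 ± 0.18 (adjusted p = 0.267) and IL33 at -0.33 ± 0.68 (adjusted p = 0.891). Of the lymphocyte markers, NKG7 rose by 0.56 ± 0.16, the only 1 of 9 NK markers to pass (1 adjusted over the list alone; camera adjusted p = 0.494). None of 7 T cell (camera adjusted p = 0.464) and none of 5 B cell markers (camera adjusted p = 0.523) passed, 0 and 0 adjusted over the list alone. Among the remaining lists, 1 of 3 Toll-like receptors rose and 1 fell, 2 adjusted over the list alone (camera adjusted p = 0.494), and 1 of 4 p53 targets rose, 1 adjusted over the list alone (camera adjusted p = 0.456). The call of IFITM1 was lost without unstimulated replicate 2 (0.63), unstimulated replicate 3 (0.55) or LPS replicate 1 (0.54), and that of NKG7 without unstimulated replicates 1 (0.53) or 3 (0.48) or LPS replicates 2 (0.55) or 3 (0.44).

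Sizes of change for genes near background depend on how the background is handled. With an offset of 50 intensity units, SERPINB4 rose by 4.71, WNT5A by 2.82, CCL19 by 2.35, CASP5 by 1.67 and FPR2 by 1.23, while MYO18A stood at -0.75, GDAP1 at -0.90 and TMA16 at -0.91, and TRIM34 no longer passed (-0.47).

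**Figure D2:**
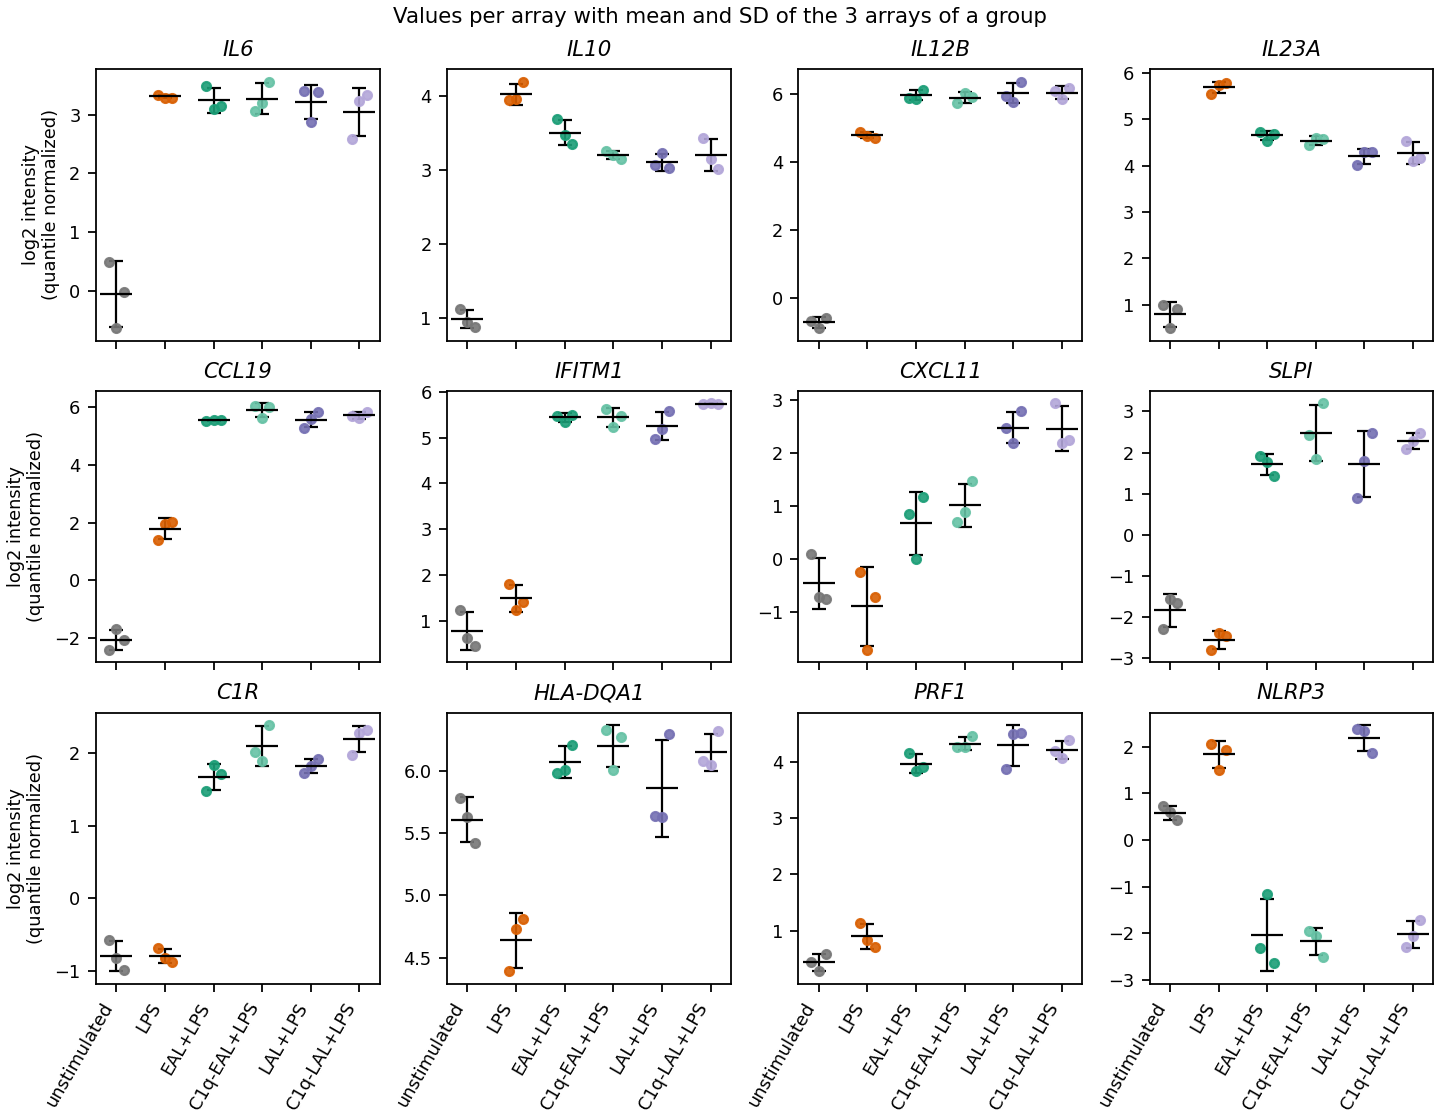
Quantile-normalized log2 intensity of 12 genes on each array, by group. Points are arrays with the mean and SD of the 3 arrays of a group; IL12B has a mean of 4.79 with LPS and 5.95 with EAL and LPS, and NLRP3 has a mean of 2.19 with LAL and LPS and of -2.02 with C1q-LAL and LPS.

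Early apoptotic lymphocytes before LPS, compared with LPS alone, raised interferon-stimulated genes. Of 9 tested, 7 rose and none fell, and 7 passed adjusted over the list alone (camera adjusted p = 1.3e-07, and 0.0227 with an estimated correlation). IFITM1, which restricts virus entry, rose by 3.96 ± 0.19 log2 (SE, n = 3 per group; adjusted p = 4.5e-11), TNFSF10, the death ligand TRAIL, by 3.51 ± 0.22, the guanylate-binding protein GBP4 by 3.37 ± 0.26 and the RNA helicase DHX58 by 1.38 ± 0.15. The channel gene CALHM6 rose by 5.42 ± 0.53 and SLPI, which inhibits leukocyte proteases, by 4.27 ± 0.36. CALHM6 started from -2.03 ± 1.04 (SD) with LPS, below the 25th percentile of gene values (-1.6), so the size of its rise with any target is uncertain. Both tested complement genes rose, C1R by 2.47 ± 0.19 and CFB by 3.34 ± 0.37. In all, 177 genes were higher and 40 lower than with LPS alone (4435 and 1563 over all probe sets).

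Markers of NK and T cells were higher in the same arrays. Of 9 NK and cytotoxic markers, 6 rose, and 8 adjusted over the list alone (camera adjusted p = 1.3e-07), with the pore-forming PRF1 at 3.06 ± 0.18, KLRB1 at 3.27 ± 0.28 and NKG7 at 2.66 ± 0.16. Of 7 T cell markers, 5 rose, and 6 adjusted over the list alone (camera adjusted p = 0.00038), among them ICOS at 3.66 ± 0.31 and CD247 at 1.52 ± 0.20. Both calls held with an estimated correlation. Of 5 B cell markers, 2 rose, and 3 adjusted over the list alone (camera adjusted p = 0.0671), with CD79A at 2.05 ± 0.27. RNA of the added lymphocytes may be part of any rise with targets given here, not only of the rise of these markers. Its share of the RNA measured could also lower the values of macrophage genes. Falls with targets were therefore not separated from it either.

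Cytokines divided. IL12B rose further with EAL, by 1.16 ± 0.15, and LTA by 1.12 ± 0.21, while IL23A fell by 1.04 ± 0.15, IL36G by 0.94 ± 0.19 and IL10 by 0.52 ± 0.15 (adjusted p = 0.0158). IL6 stood at -0.07 ± 0.25 (adjusted p = 0.942) and IL1B at -0.07 ± 0.08 (adjusted p = 0.739). IL1B had a mean of 7.4 with LPS, near the highest deposited values of the EAL arrays (7.56 to 7.73). A ceiling was therefore not excluded for IL1B in any comparison. MT1G (means of 7.17 with LPS and 7.48 with EAL), MT1F (7.14 with EAL) and CXCL10 (7.18 with LAL) also came near these values. For their changes with targets a ceiling was not excluded either. Of 8 pro-inflammatory cytokines, 2 rose and 3 fell, and 5 passed adjusted over the list alone; the median was -0.07, the mean 0.01 and the test pointed down (camera adjusted p = 0.374). NLRP3, the sensor of an inflammasome, fell by 3.87 ± 0.32 (adjusted p = 2.7e-08) and IL20 by 2.52 ± 0.35, while CASP5 rose by 1.20 ± 0.18. NLRP3 rests on 1 probe set, so its falls here and in the comparisons below are those of this probe set only. Whether other probe sets of the gene fell with EAL was not tested. The 4 inflammasome components had a median of 0.24 and a mean of -0.55, 1 rose and 1 fell, and 2 passed adjusted over the list alone (camera adjusted p = 0.404). The call of IL10 was lost without LPS replicate 3 (-0.44), EAL replicate 2 (-0.51) or EAL replicate 3 (-0.45).

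Antigen presentation and migration genes were higher with EAL. Of 5 MHC and antigen presentation genes, 3 rose, and 3 adjusted over the list alone: HLA-DQA1 by 1.42 ± 0.16, HLA-DQB1 by 1.39 ± 0.17 and TAP2, a peptide transporter, by 0.91 ± 0.11 (camera adjusted p = 0.00194). Of 8 chemokines, 5 rose, and 6 passed adjusted over the list alone (camera adjusted p = 0.00684), led by CCL19 at 3.76 ± 0.19 and CXCL11 at 1.57 ± 0.37. Of 7 chemotactic receptors, 4 rose, and 4 adjusted over the list alone (camera adjusted p = 0.00066), with FPR2 at 1.93 ± 0.31, CCR7 at 1.89 ± 0.20 and CCR4 at 1.45 ± 0.17. These calls held with an estimated correlation. The MHC and chemokine calls were lost on the values as deposited, with medians of 0.58 and 0.46, and on median-centred arrays, with 0.62 and 0.50.

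Of 7 costimulation and classical (M1) markers, 5 rose with EAL and 1 fell, and 6 passed adjusted over the list alone, with ACOD1, which makes itaconate, at 3.47 ± 0.28 and CD38 at 1.85 ± 0.15 (camera adjusted p = 0.00049; adjusted p = 0.0723 with an estimated correlation). Of 9 metallothioneins, 6 rose, and 6 adjusted over the list alone, with MT1M at 1.44 ± 0.23 (camera adjusted p = 0.00152; adjusted p = 0.176 with an estimated correlation), a call also lost on the values as deposited and on median-centred arrays. Of 6 JAK-STAT genes, 2 rose, and 2 adjusted over the list alone: IL12RB2, a chain of the IL-12 receptor, by 2.33 ± 0.20 and SOCS1 by 1.37 ± 0.18 (camera adjusted p = 0.0572). Of 8 immunoregulatory mediators, 2 rose and 1 fell, and 4 passed adjusted over the list alone (camera adjusted p = 0.374). IL1RN, the IL-1 receptor antagonist, stood at 1.29 ± 0.46 (adjusted p = 0.0714) and passed without LPS replicate 3 (1.58); IL27 at 0.14 ± 0.25 (adjusted p = 0.831), EBI3 at 0.22 ± 0.19 (adjusted p = 0.607), IL33 at 0.44 ± 0.68 (adjusted p = 0.803) and SOCS3 at 0.05 ± 0.16 (adjusted p = 0.932). CXCL10 rose by 0.91 ± 0.18, a call lost on the values as deposited (0.51) and on median-centred arrays (0.55), as was that of TLR8. TLR10 (2.01 ± 0.30) and TLR8 (0.83 ± 0.19) rose and TLR5 (-0.85 ± 0.20) fell, all 3 also adjusted over the list alone (camera adjusted p = 0.374). None of 4 p53 targets passed, 0 adjusted over the list alone; their median was 0.05, their mean -0.02 and the test pointed down (camera adjusted p = 0.726).

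With the offset of 50 intensity units, SLPI rose by 2.41, CFB by 1.84, ICOS by 1.73, KLRB1 by 1.68, TLR10 by 1.01 and CXCL11 by 0.96 with EAL, and NLRP3 stood at -2.35. Among further large falls were VNN3P (-2.06 ± 0.60), CREG2 (-1.93 ± 0.45) and PPP1R2B (-1.81 ± 0.39), with -1.21, -0.70 and -0.65 under the offset. The call of VNN3P was lost without LPS replicates 1 or 3 (-1.95 each) or EAL replicates 2 (-2.0) or 3 (-1.82).

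Late apoptotic lymphocytes raised 206 genes above LPS alone and lowered 58 (5705 and 1715 over all probe sets). CALHM6 rose by 5.55 ± 0.53 log2 (SE, n = 3 per group; adjusted p = 1.4e-07), SLPI by 4.28 ± 0.36, the immune GTPase GIMAP7 by 3.83 ± 0.26 and the ubiquitin-like UBD by 3.70 ± 0.34. Of 9 interferon-stimulated genes, 7 rose, and 7 adjusted over the list alone (camera adjusted p = 3.1e-08, and 0.0176 with an estimated correlation). IFITM1 rose by 3.76 ± 0.19, TNFSF10 by 3.66 ± 0.22 and CXCL11, a chemokine that draws activated T cells, by 3.38 ± 0.37. CFB rose by 3.53 ± 0.37 and C1R by 2.62 ± 0.19.

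NK and T cell markers were higher with LAL too. Of 9 NK and cytotoxic markers, 7 rose, and 8 adjusted over the list alone (camera adjusted p = 3.1e-08), with PRF1 at 3.39 ± 0.18 and GZMH at 2.43 ± 0.26. Of 7 T cell markers, 5 rose, and 5 adjusted over the list alone (camera adjusted p = 0.00069), with ICOS at 3.32 ± 0.31. Of 5 B cell markers, 1 rose, and 1 adjusted over the list alone (camera adjusted p = 0.403). The calls for NK and T cell markers held with an estimated correlation.

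IL12B rose by 1.23 ± 0.15 with LAL, while IL23A fell by 1.49 ± 0.15, IL36G by 1.07 ± 0.19, IL10 by 0.93 ± 0.15 and CSF2, a growth factor of myeloid cells, by 0.86 ± 0.14. IL6 stood at -0.09 ± 0.25 (adjusted p = 0.838), IL1B at -0.08 ± 0.08 (adjusted p = 0.565) and NLRP3 at 0.35 ± 0.32 (adjusted p = 0.503). Of 8 pro-inflammatory cytokines, 2 rose and 3 fell, and 5 passed adjusted over the list alone (camera adjusted p = 0.274). Of 4 inflammasome components, CASP5 rose by 1.11 ± 0.18, and 2 passed adjusted over the list alone (camera adjusted p = 0.262). IL20 fell by 2.66 ± 0.35 and VNN3P by 2.90 ± 0.60. IL27 stood at 0.56 ± 0.25 (adjusted p = 0.146) and passed without LPS replicate 1 (0.78); EBI3 stood at 0.19 ± 0.19 (adjusted p = 0.558), IL33 at -0.32 ± 0.68 (adjusted p = 0.795) and SOCS3 at 0.07 ± 0.16 (adjusted p = 0.811). Of 8 immunoregulatory mediators, 2 rose and 1 fell, and 5 passed adjusted over the list alone (camera adjusted p = 0.369).

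Of 5 MHC and antigen presentation genes, 3 rose with LAL, and 3 adjusted over the list alone (camera adjusted p = 0.00114), with HLA-DQA1 at 1.22 ± 0.16 and TAP2 at 1.16 ± 0.11. Of 8 chemokines, 5 rose and 1 fell, and 6 passed adjusted over the list alone (camera adjusted p = 0.00242), with CCL1 at 1.65 ± 0.27 and CXCL10 at 1.25 ± 0.18. Of 7 chemotactic receptors, 4 rose, and 5 adjusted over the list alone (camera adjusted p = 0.00114), with CXCR3, the receptor of CXCL10 and CXCL11, at 1.70 ± 0.33. These 3 calls held with an estimated correlation. Of 7 M1 markers, 5 rose and 1 fell, and 6 passed adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.102 with an estimated correlation). Of 9 metallothioneins, 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0277; adjusted p = 0.343 with an estimated correlation). Of 6 JAK-STAT genes, IL12RB2 (2.42 ± 0.20) and SOCS1 (1.26 ± 0.18) rose, and 2 adjusted over the list alone (camera adjusted p = 0.125). JAK3 stood at 0.23 ± 0.29 (adjusted p = 0.662); it rose by 0.76 without LAL replicate 1 and fell by 0.91 on the arrays without the mark "re", which left 1 LAL array. TLR10 and TLR8 rose and TLR5 fell, 3 adjusted over the list alone (camera adjusted p = 0.333). None of 4 p53 targets passed, 0 adjusted over the list alone (camera adjusted p = 0.377).

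With the offset, SLPI rose by 2.44, GIMAP7 by 2.49, CFB by 1.99, ICOS by 1.49 and CXCR3 by 0.92 with LAL, and VNN3P stood at -1.47. Without the marked arrays VNN3P (-2.18), CXCR3 (1.53), CASP5 (0.76), TLR10 (1.17), TLR8 (0.57) and TLR5 (-0.26) no longer passed.

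C1q-coated early targets raised 207 genes above LPS alone and lowered 38, among genes the authors selected (6468 and 2900 over all probe sets). SLPI rose by 5.05 ± 0.36 log2 (SE, n = 3 per group; adjusted p = 2.9e-09), CFB by 3.98 ± 0.37, IFITM1 by 3.96 ± 0.19, CCL19 by 4.11 ± 0.19 and C1R by 2.90 ± 0.19. IL12B rose by 1.10 ± 0.15, while IL23A fell by 1.15 ± 0.15, IL10 by 0.83 ± 0.15 and NLRP3 by 4.01 ± 0.32. IL1RN rose by 1.77 ± 0.46 (adjusted p = 0.00918) and IL27, a cytokine of the IL-12 family, by 0.93 ± 0.25 (adjusted p = 0.0118). Of the NK and T cell markers, PRF1 was higher, at 3.42 ± 0.18, and ICOS, at 3.55 ± 0.31. The call of IL27 was lost without LPS replicate 3 (0.67), C1q-EAL replicate 2 (0.84) or C1q-EAL replicate 3 (0.82), and that of IL1RN without LPS replicate 2 (1.37) or C1q-EAL replicate 3 (1.52). With the offset SLPI rose by 3.11, CFB by 2.37, ICOS by 1.66 and IL1RN by 0.81, and NLRP3 stood at -2.42.

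C1q-coated late targets raised 237 genes and lowered 59 (8370 and 3667 over all probe sets). SLPI rose by 4.84 ± 0.36 log2 (SE, n = 3 per group; adjusted p = 4.3e-09), IFITM1 by 4.25 ± 0.19, UBD by 4.02 ± 0.34, GIMAP8 by 3.77 ± 0.36 and CXCL11 by 3.35 ± 0.37. FAS, a death receptor, rose by 2.14 ± 0.54 and IL1RN by 1.61 ± 0.46. IL12B rose by 1.24 ± 0.15, and IL23A fell by 1.42 ± 0.15, CSF2 by 0.94 ± 0.14, IL10 by 0.83 ± 0.15 and NLRP3 by 3.86 ± 0.32. PRF1 (3.32 ± 0.18) and ICOS (3.93 ± 0.31) were higher too. CD6, a T cell receptor of adhesion, fell by 2.22 ± 0.75 (adjusted p = 0.0428), a call lost without C1q-LAL replicate 1 (-0.71) or without LPS replicates 1 (-2.27), 2 (-2.11) or 3 (-2.29). The call of IL1RN was lost without LPS replicate 2 (1.21) or C1q-LAL replicate 2 (1.06), and with the offset SLPI rose by 2.91, ICOS by 1.95, FAS by 0.78 and IL1RN by 0.75, and NLRP3 stood at -2.37.

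With C1q-EAL and with C1q-LAL, 7 of 9 interferon-stimulated genes rose, and 7 adjusted over the list alone (camera adjusted p = 5.9e-08 and 2.1e-08). Of 9 NK and cytotoxic markers, 8 rose with each, and 8 adjusted over the list alone (camera adjusted p = 5.9e-08 and 2.1e-08). T cell markers gave 3 and 4 of 7 that rose, with CD6 falling in the latter, and 4 and 6 adjusted over the list alone (camera adjusted p = 0.00967 and 0.0102). Of 5 MHC genes, 3 rose with each, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.00053 and 0.00294). Of 8 chemokines, 4 and 5 rose and 0 and 1 fell, and 6 and 7 passed adjusted over the list alone (camera adjusted p = 0.0066 and 0.00327). Of 7 chemotactic receptors, 4 and 5 rose, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.00216 and 0.0013). All of these camera calls held with an estimated correlation.

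Other lists with C1q-EAL and C1q-LAL were less firm. Of 7 M1 markers, 5 rose and 1 fell with each, and 6 and 7 passed adjusted over the list alone (camera adjusted p = 0.00071 and 0.00073; adjusted p = 0.0806 and 0.0746 with an estimated correlation). Of 9 metallothioneins, 5 and 7 rose, and 7 and 7 adjusted over the list alone (camera adjusted p = 0.00341 and 0.00446; adjusted p = 0.21 and 0.233 with an estimated correlation). The call with C1q-EAL was lost on the values as deposited and on median-centred arrays. Of 6 JAK-STAT genes, 2 rose with each, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.0174 and 0.0432; adjusted p = 0.12 and 0.189 with an estimated correlation). SOCS1 rose by 1.64 ± 0.18 with C1q-EAL and 1.48 ± 0.18 with C1q-LAL. Immunoregulatory mediators gave 4 and 3 of 8 that rose and 1 and 2 that fell, and 6 and 6 adjusted over the list alone (camera adjusted p = 0.191 and 0.285). Pro-inflammatory cytokines gave 2 that rose and 3 that fell with each, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.284 and 0.291).

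The remaining lists gave no camera call with C1q-EAL or C1q-LAL. Inflammasome components gave 1 that rose and 1 that fell with each, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.588 and 0.966). Their medians of 0.27 and 0.64 and means of -0.49 and -0.27 differed in sign, and both tests pointed down. Toll-like receptors gave 2 of 3 that rose with each and 1 and 0 that fell, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.284 and 0.262). B cell markers gave 2 and 1 of 5, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.378 and 0.74; with C1q-LAL the median was -0.28, the mean 0.29 and the test pointed up). The p53 targets gave 0 and 2 of 4, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.761 and 0.666). Their median and mean were 0.13 and 0.14 with C1q-EAL, where the test pointed down, and -0.03 and 0.39 with C1q-LAL, where it pointed up.

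**Figure D3:**
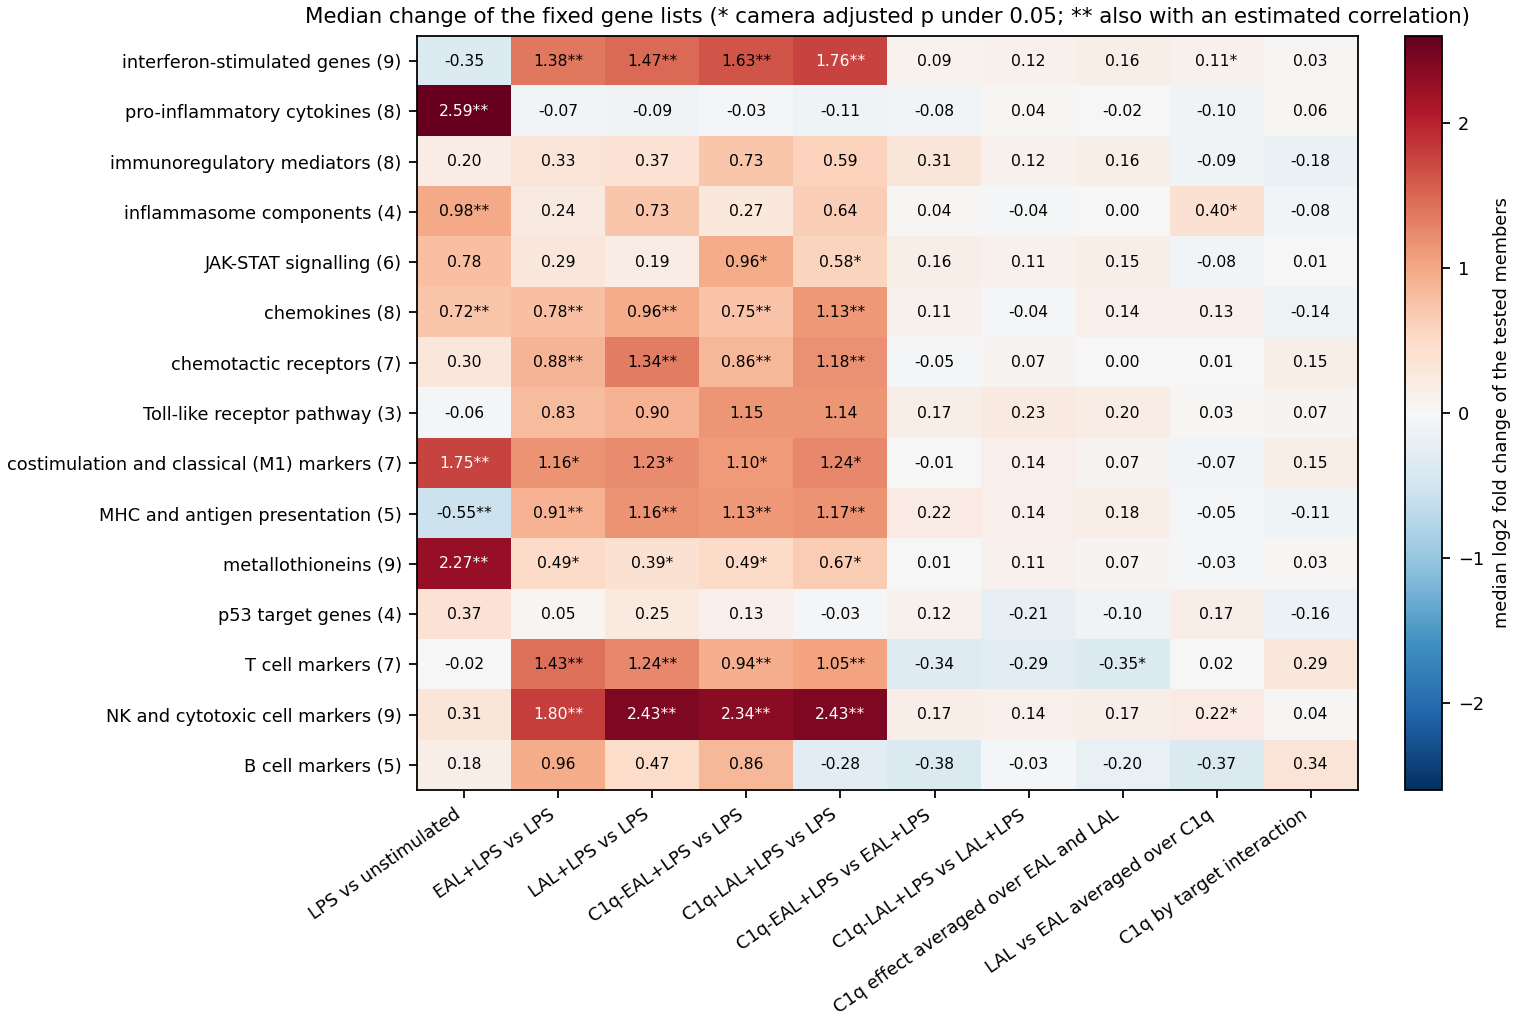
Median log2 change of the tested members of each list with at least 3 tested members (number in brackets), for 10 comparisons. Stars mark camera calls as the title states; interferon-stimulated genes have medians of 1.38, 1.47, 1.63 and 1.76 in the target groups against LPS, and 0.09 and 0.12 for C1q on either target.

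The target groups shared much of their change, in comparisons that use the same LPS arrays. EAL and LAL had 158 genes higher than LPS in both, where independent sets would give 24.3, and 17 lower in both against 1.5. Across genes, which are not independent replicates, their changes had r = 0.85. Noise alone gave r = 0.5 in 50 simulations, a value that sharing the LPS arrays fixes in advance. The covariance of the changes was 0.544, against 0.065 in the simulations. Part of the excess of shared genes may come from these controls, because 3 arrays are too few to split. In all 4 target groups, 147 genes were higher than with LPS, and 10 lower. Of the 21 tested T, NK and B cell markers, 10 (47.6%) were among the former, against 9.8% of all genes.

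Compared with unstimulated macrophages, as in the submitters' design, 300 genes were higher and 62 lower with EAL, 318 and 55 with C1q-EAL, 320 and 72 with LAL, and 332 and 75 with C1q-LAL. These genes are a selection by the authors: over all probe sets past the filter the split was more even, with 8216 higher and 6021 lower, 9686 and 6635, 8838 and 4281, and 11053 and 7101 in that order. SERPINB4 rose by 9.63 ± 0.26, 9.80 ± 0.26, 9.44 ± 0.26 and 9.16 ± 0.26 log2 for EAL, C1q-EAL, LAL and C1q-LAL (SE, n = 3 per group). CCL19 rose by 7.62 ± 0.19 to 7.97 ± 0.19 and IL12B by 6.59 ± 0.15 to 6.74 ± 0.15. IL10 remained above unstimulated, by 2.12 ± 0.15 to 2.52 ± 0.15, and IL6 by 3.10 ± 0.25 to 3.32 ± 0.25. NLRP3 fell by 2.62 ± 0.32 with EAL, 2.75 ± 0.32 with C1q-EAL and 2.61 ± 0.32 with C1q-LAL, and rose by 1.61 ± 0.32 with LAL. TREM2 fell by 0.91 ± 0.16 to 1.35 ± 0.16. Camera called 10, 9, 11 and 9 of 15 lists, of which 7, 8, 10 and 8 held with an estimated correlation. With the offset, SERPINB4 rose by 6.27, 6.44, 6.09 and 5.82, and NLRP3 stood at -1.34, -1.41 and -1.36 in the groups where it fell.

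C1q on early targets changed no gene past the threshold in limma, with 88 of 1498 genes at an unadjusted p under 0.05 (smallest adjusted p = 0.264). The genes with the smallest p were BMPER (-1.32 ± 0.30), SPANXE (-1.02 ± 0.23), RHEX (-1.46 ± 0.37), ALDH1A3 (-1.53 ± 0.40) and ID2 (-0.84 ± 0.22; SE, n = 3 per group). IL10 stood at -0.30 ± 0.15 (95% interval -0.61 to 0.00), IL12B at -0.07 ± 0.15 (-0.38 to 0.24) and IL6 at 0.03 ± 0.25 (-0.49 to 0.55). IL27 stood at 0.79 ± 0.25 (0.26 to 1.31; adjusted p = 0.597) and NLRP3 at -0.13 ± 0.32 (-0.81 to 0.54). NLRP3 lay near background with EAL and with C1q-EAL (means of -2.04 and -2.17), so its interval does not bound a fall with C1q. The submitters' analysis of variance gave 0 genes with either adjustment, and without C1q-EAL replicate 1 limma gave 1, BMPER (-1.68). No list passed; the nearest were T cell markers, with a median of -0.34 (camera adjusted p = 0.0513), and MHC genes, at 0.22, and B cell markers, at -0.38 (camera adjusted p = 0.109 each). On the values as deposited and on median-centred arrays, MHC genes and NK markers passed up and T cell markers down.

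C1q on late targets changed 1 gene, NLRP3, by -4.22 ± 0.32 log2 (SE, n = 3 per group; 95% interval -4.89 to -3.55; adjusted p = 9.8e-08). Its mean was 2.19 ± 0.28 (SD) with LAL and -2.02 ± 0.29 with C1q-LAL, and the groups did not overlap. Next were MPIG6B (-2.05 ± 0.41, adjusted p = 0.0652), NBPF4 (-1.52 ± 0.39), GPR153 (-1.22 ± 0.31) and TFF1 (-1.10 ± 0.29). IL10 stood at 0.10 ± 0.15 (-0.21 to 0.40), IL12B at 0.01 ± 0.15 (-0.30 to 0.32), IL6 at -0.17 ± 0.25 (-0.69 to 0.35) and IL1B at 0.11 ± 0.08 (-0.06 to 0.29). NLRP3 fell by 2.69 with the offset. The count was 3 without C1q-LAL replicate 3, where GPR153 passed too (-1.60), 2 without LAL replicate 1 (1 higher, 1 lower), 2 with array weights, where MPIG6B passed (-2.21), and 4 on arrays without the mark "re" (3 higher, 1 lower). No list passed; the nearest were inflammasome components, M1 markers, metallothioneins and T cell markers (camera adjusted p = 0.307 each).

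**Figure D4:**
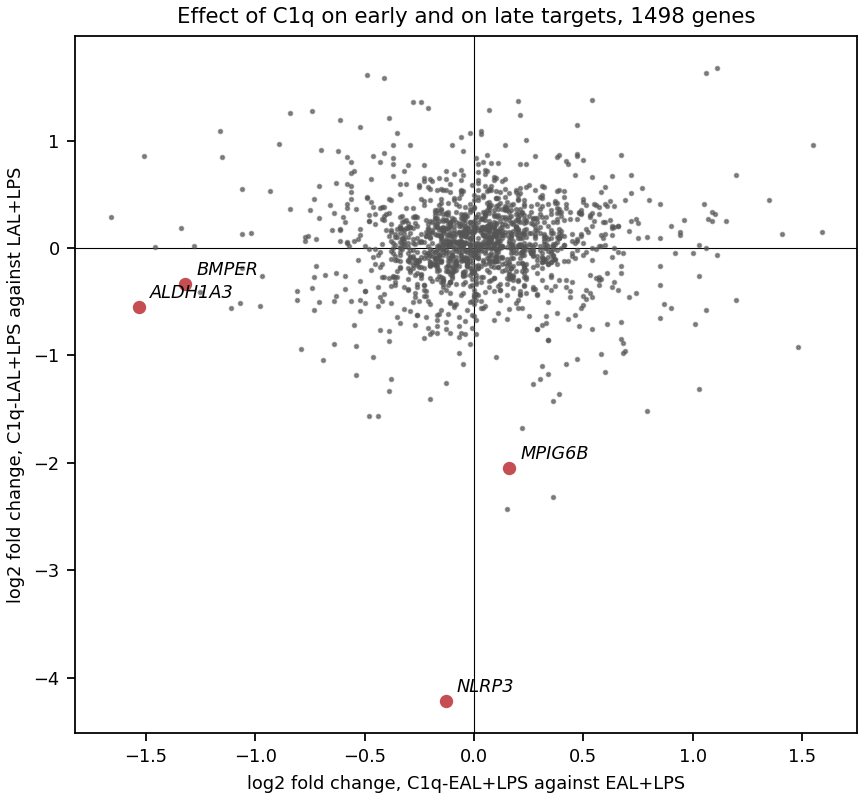
Log2 change with C1q on early targets (horizontal axis) and on late targets (vertical axis) for 1498 genes, each point a gene. The correlation across genes is 0, and NLRP3 lies at -0.13 and -4.22.

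The changes with C1q on the 2 targets were uncorrelated across genes, which are not independent replicates (Pearson r = 0, Spearman rho = 0.04), and 53.7% of genes had the same sign. At an unadjusted p under 0.05 in both were 9 genes, where chance gives 6.5, and 6 of them had the same sign. Averaged over both targets, C1q changed NLRP3 by -2.18 ± 0.23 (adjusted p = 1.7e-05), a mean of unlike changes, and no other of 1498 genes. T cell markers, with a median of -0.35, passed camera down (adjusted p = 0.00952; adjusted p = 0.0628 with an estimated correlation) while 0 of 7 members passed the gene test and 0 adjusted over the list alone. The list call held in each of the 12 settings that left out 1 array (adjusted p from 0.00137 without C1q-LAL replicate 1 to 0.0422 without C1q-LAL replicate 2), but single members moved: CD6 stood at -1.14 ± 0.53 (-0.38 without C1q-LAL replicate 1), SKAP1 at -0.63 ± 0.29 (-0.35 without the mark "re"), TRAT1 at -0.55 ± 0.19 and CD247 at -0.35 ± 0.14 (-0.11 without the mark). NK markers had a median of 0.17 (camera adjusted p = 0.181) and B cell markers of -0.20 (camera adjusted p = 0.181). The interaction of C1q with the kind of target passed for NLRP3 alone, at -4.08 ± 0.45 (SE over 4 groups of n = 3; adjusted p = 4.6e-05), and next came NBPF4 at -2.31 ± 0.55 (adjusted p = 0.343). NLRP3 lay near background with EAL and with C1q-EAL (means of -2.04 and -2.17), where a fall could hardly be measured. Its interaction therefore does not show that C1q acts differently on the 2 targets. With the offset NLRP3 stood at -2.62 for the interaction and -1.38 for the average. No list passed for the interaction (smallest camera adjusted p = 0.223, inflammasome components), and none but T cell markers for the average, where MHC genes passed up on median-centred arrays (median 0.23, camera adjusted p = 0.0395; main analysis 0.18 and 0.208).

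Late against early targets, averaged over C1q, raised 3 of 1498 genes. NLRP3 was higher by 2.19 ± 0.23 log2 (adjusted p = 1.6e-05; n = 6 per side), which rests on the groups without C1q, and by 1.35 with the offset. CXCL11 was higher by 1.63 ± 0.26 (adjusted p = 0.00439), and APOBEC3A, a cytidine deaminase of antiviral defence, by 0.75 ± 0.14 (adjusted p = 0.0164). IL23A stood at -0.36 ± 0.10 (adjusted p = 0.158) and IL10 at -0.20 ± 0.10 (adjusted p = 0.333). Interferon-stimulated genes had a median of 0.11, with 1 of 9 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.0428; adjusted p = 0.339 with an estimated correlation). Inflammasome components, at 0.40, held 1 of 4 and 1 adjusted over the list alone (camera adjusted p = 0.0358; adjusted p = 0.104 with an estimated correlation). NK and cytotoxic markers, at 0.22, held 0 of 9 and 0 adjusted over the list alone (camera adjusted p = 0.0424; adjusted p = 0.104 with an estimated correlation). The count was 11 on the values as deposited (10 higher, 1 lower), 14 on median-centred arrays (13 and 1), 8 without EAL replicate 3 (5 and 3) and 16 on arrays without the mark "re" (5 and 11), so the direction over genes depends on the setting. On the deposited and on the median-centred scale 5 more lists passed, among them M1 markers (median -0.07, against 0.35 and 0.27 on those scales) and MHC genes (-0.05, against 0.30 and 0.23). The call of APOBEC3A was lost in 6 of the 12 settings that left out 1 array: EAL replicate 1 (0.69), C1q-EAL replicates 1 (0.71) and 2 (0.72), LAL replicates 1 and 2 (0.71 each) and C1q-LAL replicate 3 (0.70).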

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

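The tests of background and of neighbouring probe sets for NLRP3, the test of lymphocyte markers against random lists, and the count of splits that keep the division of LAL and C1q-LAL, were chosen only after the results they concern were seen.

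NLRP3 stands out because its change with C1q differed between the 2 kinds of target: the interaction was -4.08 ± 0.45 log2 (limma adjusted p = 4.6e-05), with -0.13 ± 0.32 on early and -4.22 ± 0.32 on late targets. In 3 of 3 arrays it was high with LAL (mean 2.19 ± 0.28, SD) and in 3 of 3 low with C1q-LAL (-2.02 ± 0.29), close to EAL (-2.04 ± 0.78) and C1q-EAL (-2.17 ± 0.29). Its lowest group mean lay at percentile 15.3 of all probe sets. With EAL it was thus near background before C1q, where a further fall could hardly be measured. The interaction therefore cannot show that C1q acts differently on the 2 kinds of target. Signal near background may change the size, but with the offset of 50 intensity units the interaction was still -2.62 and the change on late targets -2.69. These values argue against background as the whole cause of the fall on late targets. The offset does not answer whether a fall on early targets was hidden. The behaviour of a single probe set stays open. Of the 20 probe sets with the nearest numbers, 10 rose by over 1 log2 with LPS, but only 2 fell by over 1 log2 with C1q on late targets. If these 20 read NLRP3, the few falls go with the behaviour of 1 probe set. Of all probe sets 2 passed for C1q on late targets, NLRP3 and 1 of these 20, at -1.26 log2 (limma adjusted p = 0.00497). That second probe set goes the other way if it reads the same gene. As 0 of the 20 carry a gene name, they cannot decide. A response of the macrophages to C1q on late targets was not tested apart from this and stays open too.

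T cell and NK markers passed camera up with all 4 targets and B cell markers with none (camera adjusted p = 0.0671 with EAL, 0.403 with LAL, 0.378 with C1q-EAL and 0.74 with C1q-LAL, where their median was -0.28). Over the 4 target groups against LPS, the 21 tested T, NK and B cell markers had a median change of 1.04 log2 (95th percentile of 10000 random lists 0.19), which restates the rise, so RNA of the added lymphocytes and expression by the macrophages cannot be told apart. The mean level of NKG7 went from 2.06 with LPS to between 4.71 and 5.01 with targets, and that of CD3D, chosen after its values were seen, from -2.03 with LPS to between -1.17 and -0.75, without passing in any of the 4. Of the 21 markers, 0 are held by another list, and all were picked by the authors from these arrays. The labels name no wash or sort that would remove the lymphocytes, and both explanations stay open.

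With C1q the T cell markers had a mean change of -0.41 ± 0.16 log2 (SE over 7 genes; 6 of 7 below 0), the NK markers 0.18 ± 0.04 (1 of 9 below 0) and the B cell markers -0.24 ± 0.15 (4 of 5 below 0). The errors are over genes of the same arrays, not over replicates. Less lymphocyte RNA with C1q would lower all of these if all read lymphocyte RNA. The NK median of 0.17 goes against it only on that condition, which could not be told from expression by the macrophages. The NK list also did not pass (camera adjusted p = 0.181), so less lymphocyte RNA is not excluded. A change in the make-up of the lymphocytes stays open too, and the T cell call itself was lost with an estimated correlation.

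C1q-LAL replicate 1 lay apart from the other arrays, with a mean correlation of 0.925 against 0.95 to 0.963 for the other 17, and of 0.818 against 0.886 to 0.939 over the 63330 brightest probe sets.

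Other splits of the same arrays were run for each count of genes. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 160 and 0 for LPS against unstimulated, 217 and 1 for EAL, 264 and 2 for LAL, 245 and 0 for C1q-EAL and 296 and 0 for C1q-LAL against LPS. They were 0 and 0 for C1q on early targets, 1 and 1 for C1q on late targets, and 362 and 0, 392 and 0, 373 and 0 and 407 and 1 for EAL, LAL, C1q-EAL and C1q-LAL against unstimulated. Of 100 splits within pairs of groups, 13 gave as many genes as the averaged C1q effect (real 1, highest other 1) and 11 as many as the interaction (real 1, highest other 1), but 11 of the 100 keep the real division of LAL and C1q-LAL arrays or its mirror, and all 11 gave as many in both tests, so a share under 0.05 could not be reached for a difference within that pair and these 2 counts decide nothing. For LAL against EAL only the real split gave 3 genes, and the highest other gave 2.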

How the results depend on the processing

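The offset, all probe sets, the arrays without the mark "re", and the leave-one-out and scaling runs of the list tests and leave-one-out runs of the correlation were chosen only after seeing the data. Over 831 results for named genes and 31 settings, 15942 of 16648 comparisons kept their side of the threshold (244 of these, not called in either, changed sign), 628 lost their call, 76 gained one and 2, not called before, passed with the other sign: KLF4 with C1q-EAL against unstimulated, from -0.05 to 1.02 with the probe set of the highest mean, and JAK3 with LAL against LPS, from 0.23 to -0.91 without the mark "re". The first rests on 2 probe sets that differ. The other rests on LAL replicate 1, the only LAL array left in that setting. JAK3 had an SD of 1 log2 over the 3 LAL arrays. Counts without a filter, with the 50th percentile filter, with the replicate block, with "re" as a covariate, with only the arrays compared, with the offset and without C1q-LAL replicate 1 stayed within 1.5 times of those reported. Other counts moved, and the cause was not tested unless named. LAL against EAL gave 11 on the values as deposited, 14 on median-centred arrays, 5 with array weights, 6 with the analysis of variance and Benjamini-Hochberg adjustment and 1 with Holm. Array weights gave 2 for C1q on late targets. Holm, stricter by construction, gave 67 for LPS against unstimulated, 74 (EAL), 81 (LAL), 79 (C1q-EAL) and 92 (C1q-LAL) against LPS, and 150, 165, 163 and 170 for these 4 against unstimulated. Without the mark "re", with the lone LAL array assumed to vary like the others, C1q on late targets gave 4 (3 higher), the averaged C1q effect 2 (1 higher), LAL against EAL 16 (5 higher, 11 lower) and the interaction 4 (3 higher). All 210130 probe sets past the filter, a far larger number tested, gave 3554 for LPS against unstimulated, 5998 (EAL), 7420 (LAL), 9368 (C1q-EAL) and 12037 (C1q-LAL) against LPS, 14237, 13119, 16321 and 18154 for these 4 against unstimulated, 2 for C1q on late targets, 4 for its average and 1 for LAL against EAL. Of these, 123 carried a gene name for LPS against unstimulated, and 167 (EAL), 180 (LAL), 186 (C1q-EAL) and 205 (C1q-LAL) against LPS. Adjusted over 1498 genes, the calls numbered 160, 217, 264, 245 and 296 in that order. Part of the named calls was therefore lost with all probe sets. Leaving out 1 array gave 135 to 179 for LPS against unstimulated, 188 to 208 (EAL), 199 to 329 (LAL), 195 to 225 (C1q-EAL) and 229 to 291 (C1q-LAL) against LPS, and 316 to 334, 339 to 364, 326 to 354 and 363 to 385 for these 4 against unstimulated. It gave 0 to 1 for C1q on early targets (1 without C1q-EAL replicate 1), 1 to 3 on late targets (3 without C1q-LAL replicate 3), 2 to 8 for LAL against EAL (8 without EAL replicate 3), and 1 for the averaged effect and for the interaction. List calls numbered 83 over 14 comparisons, 131 with fry, 63 with an estimated correlation, 87 without a filter or as deposited, 90 on centred arrays (79 shared with each scale) and 80 to 88 with 1 array left out. The correlation of the C1q effects was 0.04 with the 50th percentile filter and -0.04 to 0.02 with 1 array left out. The authors' other table holds no values per array, so that alternative was not run, and a median over probe sets was replaced by the highest. Background limits the sizes: the offset moved 13 of 52 named calls of LPS against unstimulated and 16 of 60 of EAL against LPS by over 1.5 times.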

Other observations

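The comparison with the authors' deposited table given below was chosen only after the data were seen. Lists with 1 or 2 tested members add further genes. BCL2L11, which promotes apoptosis, rose against LPS alone by 0.77 ± 0.20 log2 with EAL, 1.19 ± 0.20 with LAL, 1.00 ± 0.20 with C1q-EAL and 1.03 ± 0.20 with C1q-LAL (SE, n = 3 per group; limma adjusted p = 0.00906, 0.00014, 0.00093 and 0.00065). Its call with EAL was lost on the values as deposited (0.56), on median-centred arrays (0.60) and without EAL replicate 2 (0.68). With LPS against unstimulated macrophages, ZC3H12A, an RNase that degrades cytokine transcripts, rose by 0.95 ± 0.16, PFKFB3, a regulator of glycolysis, by 1.04 ± 0.13 and the immediate early gene BTG2 by 0.53 ± 0.08. TRAF2 stood at -0.11 ± 0.18 and KLF4, whose 2 probe sets differ, at -0.33 ± 0.21. IL17RB, a receptor chain for IL-25 listed with alternative (M2) markers, rose against LPS by 0.74 ± 0.24 with EAL, 0.98 ± 0.24 with LAL, 1.08 ± 0.24 with C1q-EAL and 0.82 ± 0.24 with C1q-LAL (limma adjusted p = 0.0473, 0.00683, 0.00292 and 0.0206), calls all lost on arrays without the mark "re" (0.45, 0.91, 0.78 and 0.53). Its calls were also lost without LPS replicate 1 with EAL (0.45) and C1q-LAL (0.53), without LPS replicate 3 (0.82) or any 1 EAL array (0.80, 0.78 and 0.65) with EAL, and without C1q-LAL replicate 1 with C1q-LAL (0.70). MAF of that list did not pass, at -0.03 ± 0.32, 0.67 ± 0.32, 0.54 ± 0.32 and 0.38 ± 0.32 in the same order of groups.

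TREM2 fell by 0.62 ± 0.16 with EAL against LPS and did not pass with LAL (-0.34 ± 0.16, limma adjusted p = 0.159), C1q-EAL (-0.38 ± 0.16, 0.124) or C1q-LAL (-0.17 ± 0.16, 0.514). TIMD4, a receptor for phosphatidylserine on dying cells, rose with C1q-LAL by 1.24 ± 0.41 (limma adjusted p = 0.0359), a call lost without LPS replicates 2 (0.99) or 3 (1.18) or C1q-LAL replicates 2 (1.05) or 3 (1.24). NFE2L2, the only tested gene of its list, stood at -0.13, -0.07, -0.12, -0.02 and 0.09 for LPS against unstimulated and for EAL, LAL, C1q-EAL and C1q-LAL against LPS.

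In the authors' deposited table, on its unstated scale, NLRP3 has 1.44 with LPS, -1.11 with EAL, -1.09 with C1q-EAL, 1.47 with LAL and -0.885 with C1q-LAL, the same signs as in the value table. IL10, IL12B, IL6 and IL27 are positive in all 5 groups in both tables. IL23A, CCR7, CCL5, SOCS1, SOCS3 and MMP3 have negative values in the authors' table in all 5 groups and positive changes in the value table. The first 3 principal components held 47.3%, 10.3% and 6.6% of the variance.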
